A study of Mus musculus with 4 samples.

How the data were processed

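Gene expression was measured on 4 Affymetrix Mouse Gene 1.0 ST arrays, 1 per RNA sample. This array carries probes spread along whole transcripts. The RNA came from Flt3-negative LSK cells (lineage-negative, Sca-1 positive, c-Kit positive bone marrow cells that lack surface Flt3, a fraction rich in hematopoietic stem cells). The cells were sorted 4 days after the final injection of pIpC, a double-stranded RNA analogue that switches on the Mx1-Cre recombinase. Per the labels, mice were 6 to 8 weeks old, from a stock crossed for 4 generations to C57BL/6, and 800 pg to 50 ng of RNA entered a whole-transcript amplification. Control mice carried 1 floxed and 1 wild-type Gabpa allele, and mice labelled GABPα-deficient carried 1 floxed and 1 null allele. Each group had 2 arrays. The labels do not say whether a sample came from 1 animal or from a pool.

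The deposited values were log2 expression values, 1 per probe set, and the submitters' processing notes name RMA and Partek without versions. RMA corrects background, quantile-normalizes and summarises probes into probe sets, and its values are on the log2 scale. The range of the table, from 1.98 to 13.7, fitted that scale, so no logarithm and no further normalization was applied. The genome build and the annotation used by the authors are not given in the sources used here, so no coordinates are printed. All 4 value columns were matched to a sample, and 0 were left over. Array data carry no read depth, and no detection calls were used here, so the small number of arrays limits the precision.

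Probe sets were named from the platform's annotation table, with symbols looked up by Entrez gene number in the RefSeq gene table of the mouse assembly GRCm38.p6. Of the 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had none. Genes were named only from probe sets with 1 symbol, which covered 19939 genes. Where a gene had several such probe sets, the one with the highest mean over all 4 arrays stood for it.

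The arrays labelled deficient were compared with the control arrays in R 4.3.3 with limma 3.58.1. The fit used lmFit and eBayes with genotype as its only term, and Benjamini-Hochberg adjustment over all 35556 probe sets. A probe set was called at an adjusted p under 0.05. Differences are log2 means of the arrays labelled deficient minus those of the controls, with the standard error (SE) of limma's moderated fit. Group values are means with the SD over 2 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

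Gene groups were tested with limma's camera, which ranks a list against all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 33 lists. The lists, which shared some genes, held 840 different genes, of which 772 had a single-gene probe set. They covered GABP subunits, other ETS factors, stem cell transcription factors and surface markers, quiescence and FOXO genes, the BCL2 family, p53 targets, DNA repair, DNA replication, mitosis, G1 cyclins and CDKs, and chromatin regulators. Further lists covered nuclear-encoded oxidative phosphorylation genes, the mitochondrial ribosome, mitochondrial gene expression and import, the cytosolic ribosome, splicing, aminoacyl-tRNA synthetases, glycolysis, interferon-stimulated genes, immediate early genes and ATF4 targets. Cell type lists covered erythroid, megakaryocyte, granulocyte and monocyte, multipotent and lymphoid progenitor, B, T and NK, mast cell, basophil and eosinophil, dendritic, macrophage, and stromal and endothelial cells. The last list held genes that the study itself has examined. The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined.

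The rule named the GABP subunits, the genes of the study's own list, and Ly6a, Kit and Flt3 from the sorting gate, whatever their values. It also named the 15 genes with the largest difference in each direction among called probe sets whose groups did not overlap. Where fewer passed, the rule filled the list in order of unadjusted p, again only with genes whose groups did not overlap, as values only. Within each list it took up to 4 members with the smallest unadjusted p. Any member past the threshold could also be named. Rhd, Pf4, Gfi1b, Jam3 and Gata1 fall outside the rule and were named after their values were seen.

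The procedure was tested on simulated data with the size and spread of this table, in 20 simulations with 200 changed probe sets among 35556. At an adjusted p under 0.05, limma called 0% of probe sets changed by a log2 of 1, 0% at 2, 18% at 3 and 43.6% at 4. At an unadjusted p under 0.05 the shares were 80.5%, 94.8%, 97.7% and 98.1%. Without any simulated change, the mean was 0.15 calls. Among 19939 simulated genes, camera with the preset correlation called a list of 20 genes shifted by a log2 of 1 in 100% of simulations and called 0 of 33 unchanged lists. With an estimated correlation it called the shifted list in 0% of simulations. Simulated genes varied independently of each other, so the 0 unchanged lists called say nothing about lists whose genes vary together. Among the lists called in the data, the estimated correlation ran from −0.092 for the study's own list to 0.517 for oxidative phosphorylation.

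The alternatives were a second quantile normalization, cyclic loess, subtraction of each column's median, removal of the dimmest 25% or of the dimmer 50% of probe sets, and single-symbol probe sets only. Others were the mean of a gene's probe sets, eBayes with a trend and robust settings, array weights, a replicate block, each array left out in turn, other thresholds, camera with an estimated correlation, and fry. With 1 array left out, the lone array of a group is assumed to vary like the other group's pair. A correction for genomic gene span was chosen after seeing the data.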

Results

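The data covered 4 arrays of Flt3-negative LSK cells from mouse bone marrow, 2 from control mice and 2 from mice labelled GABPα-deficient, all given pIpC. The median log2 value was 5.87 and 5.91 on the control arrays and 5.93 and 6.01 on those labelled deficient. Across probe sets, which are not independent replicates, the correlation was 0.960 between the control arrays and 0.944 between those labelled deficient. Between the groups it ran from 0.923 to 0.942. The p-values measure only the spread between these samples, since nothing in the labels says that they came from separate animals.

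The comparison asked how gene expression in stem-cell-enriched bone marrow differs between mice labelled GABPα-deficient and controls after pIpC. The controls carried 1 floxed and 1 wild-type Gabpa allele, so the reference was not fully wild-type. Gabpa encodes the DNA-binding subunit of GABP, an ETS-family transcription factor that also works with β subunits encoded by Gabpb1 and Gabpb2. On the arrays labelled deficient, stem cell transcription factors, stem cell surface markers, ETS factors, megakaryocyte genes and chromatin regulators fell as lists. Erythroid, macrophage and stromal markers and mitochondrial ribosome genes rose as lists. The mitochondrial ribosome call was lost without deficient replicate 1. The estimated correlation between its genes was 0.42, against 0.23 for stromal and endothelial, 0.17 for macrophage and −0.075 for erythroid markers. The preset value was 0.01, and of the lists that rose fry called only erythroid markers. The list calls held with a preset correlation between genes, and 0 of 33 lists passed with an estimated one, where the lowest adjusted p was 0.167. No single probe set passed the adjusted threshold, so single genes below are given as values.

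The Gabpa probe set (10436678) read 8.43 and 7.28 on the control arrays and 6.43 and 7.85 on the arrays labelled deficient. The means were 7.85 ± 0.82 (SD, n = 2) and 7.14 ± 1.01, a log2 difference of −0.71 (SE 0.68, limma adjusted p = 0.605). Replicate 2 labelled deficient thus lay above control replicate 2, and the probe set did not separate the groups. Without deficient replicate 1 the Gabpa log2 difference was 0.0021 and without deficient replicate 2 −1.42, and it was −0.13 and −1.29 without control replicates 1 and 2. A whole-transcript probe set can lie partly or wholly outside the deleted exons, whose position is not given in the sources used here, so it may check nothing about the deletion. The groups are therefore called by their labels throughout. Gabpb1 differed by −0.67 (SE 0.39) and Gabpb2 by −0.28 (SE 0.31). Without control replicate 1 the Gabpb1 log2 difference was −0.17 and the Gabpb2 log2 difference 0.098, and without control replicate 2 they were −1.17 and −0.65. The list of these 3 subunits was not called (camera adjusted p = 0.0989), though it passed without control replicate 2 (adjusted p = 0.00595).

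For Kit and Flt3, genes of the sorting gate, the groups did not overlap, as for 52.9% of all probe sets, and neither passed the adjusted threshold. Both were lower on the arrays labelled deficient. Whether they fell within the sorted cells or through a different mix of cells was not tested. Kit, the stem cell factor receptor used to sort the cells, read 10.21 ± 0.0017 on the control arrays and 8.10 ± 0.56 on those labelled deficient (difference −2.11, SE 0.32, adjusted p = 0.288). Flt3, the receptor whose surface protein was excluded by the gate, read 8.85 ± 0.59 and 5.81 ± 0.20 (difference −3.03, SE 0.35, adjusted p = 0.222). Ly6a, which encodes Sca-1, had no single-gene probe set and was not analysed here.

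In limma's fit 0 probe sets were lower and 0 were higher at an adjusted p under 0.05, with a lowest adjusted p of 0.169. At an unadjusted p under 0.05, 1865 were lower and 2360 higher on the arrays labelled deficient, 4225 in all, where chance alone gives 1777.8. Cyclic loess turned that split to 2349 lower and 1191 higher, and subtraction of column medians to 2185 and 1537. Leaving out control replicate 1 gave 1590 and 714, leaving out control replicate 2 gave 2295 and 1053, and a replicate block gave 1666 and 1341. The groups did not overlap for 18814 probe sets (52.9%), where chance gives 33.3%. The median difference of all probe sets was 0.15, and cyclic loess moved it to −0.0045, so list medians are also given relative to it. The shift varied with level. The lower quartile was 4.68 and 4.73 on the control arrays and 4.77 and 4.86 on those labelled deficient. The upper quartile was 7.39 and 7.33, against 7.24 and 7.18. Without the dimmer 50% of probe sets the median was 0.079, so relative medians can overstate falls and understate rises of bright genes.

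Among single genes with the smallest unadjusted p, Cd34, a sialomucin of stem and progenitor cells, read 11.30 ± 0.0023 on the control arrays and 7.77 ± 0.33 on those labelled deficient (difference −3.54, SE 0.22, adjusted p = 0.169). Muc13, a cell surface mucin, differed by −2.65 (SE 0.14), with an SD of 0.0059 on the control arrays and 0.019 on those labelled deficient. Adgrg1, the adhesion receptor GPR56 of stem cells, differed by −2.06 (SE 0.15). As3mt, an arsenic methyltransferase, differed by −3.41 and Ak4, a mitochondrial adenylate kinase, by −3.21. Smurf2, a ubiquitin ligase of TGF-β signalling, differed by −3.00, Tceal1 by −2.64, Bmt2 by −2.57, and Dapp1, an adaptor of lymphocyte signalling, by −2.45. The pseudogene Gpr137b-ps differed by −2.41, Tacc1 by −2.29, Alg11, a mannosyltransferase, by −2.02, Avl9 by −2.004, Ccdc125 by −1.96 and Atl3 by −1.81. Adjusted p for these 15 genes was 0.169 to 0.173. The rule took only genes whose groups did not overlap, so their separation is no result.

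On the other side, Sfrp4, a secreted Wnt antagonist, read 4.92 ± 0.14 on the control arrays and 9.01 ± 0.013 on those labelled deficient (difference 4.09, SE 0.15, adjusted p = 0.169). Cldn13, a claudin, read 8.14 ± 0.11 and 11.84 ± 0.068 (difference 3.69, SE 0.15). Sparc, a matrix glycoprotein of stromal cells, differed by 3.80 (SE 0.24). Ubd, a ubiquitin-like modifier, differed by 3.25, Mt2, a metallothionein, by 3.25, and Blvrb, biliverdin reductase B, by 2.96. Crip2 differed by 2.78, Atp1b2 by 2.74, Emc9 by 2.54 and Ctse, cathepsin E, by 2.53. Slc11a2, an iron transporter, differed by 2.39, Ank1, the ankyrin of red cells, by 2.13, Mmp14, a membrane metalloproteinase, by 2.001, and Klf1, an erythroid transcription factor, by 1.77. A variable segment of the immunoglobulin kappa chain differed by 6.32 (SE 0.35) on probe set 10545177 and by −0.015 (SE 0.20) on probe set 10545182, so its probe sets disagreed. Adjusted p for the probe sets that stood for these 15 genes, 10545177 among them, was 0.169 to 0.173, against 0.973 for probe set 10545182. The rule took only genes whose groups did not overlap, so their separation is no result.

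**Figure D1:**
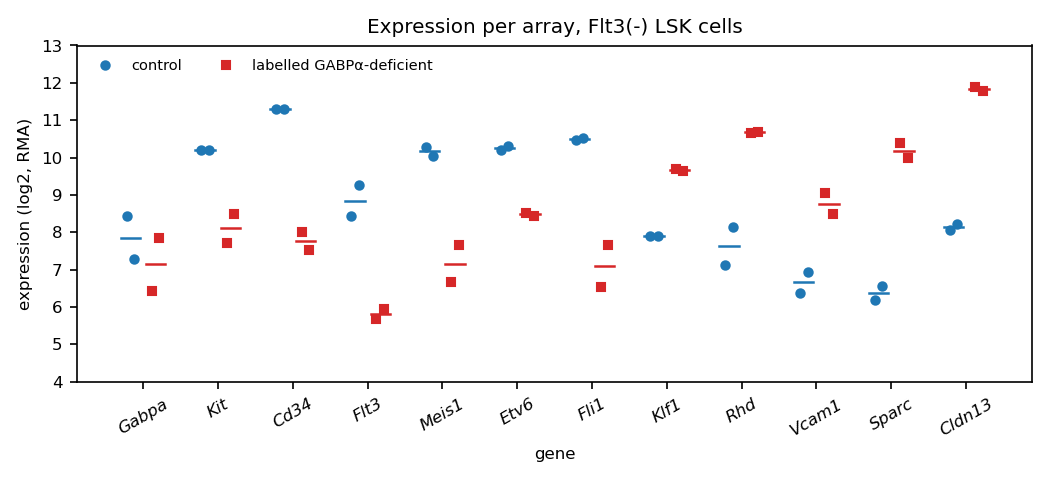
Log2 expression (vertical axis) of 12 genes (horizontal axis) on each of the 4 arrays, with 2 control arrays as circles and 2 arrays labelled GABPα-deficient as squares, and lines at the group means. The groups overlap for Gabpa and are apart for the other genes, with Cd34 at 11.30 and 7.77 and Rhd at 7.64 and 10.67. Most of these genes were named for a small unadjusted p or after their values were seen. The groups were apart for 52.9% of all probe sets, so the separation shown is no result.

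The list of stem cell transcription factors fell (camera adjusted p = 4.45e-07), with adjusted p = 0.167 with an estimated correlation. Its median over 25 measured genes was −0.52, or −0.66 relative to all probe sets. At an unadjusted p under 0.05, 10 were lower and 1 higher. Adjusted over the list alone, 4 were lower and 0 higher, and over all probe sets 0 passed. Meis1, a homeobox factor of stem cell maintenance, read 10.17 ± 0.17 and 7.16 ± 0.70 (difference −3.01, SE 0.39). Hhex, a homeobox factor of blood progenitors, differed by −1.92 (SE 0.19), Hlf, a stem cell bZIP factor, by −1.67 (SE 0.32), and Zfp36l2, an mRNA decay factor, by −0.93 (SE 0.17). Gfi1b, a repressor in erythroid and megakaryocyte cells, had the opposite sign at 0.81 (SE 0.18).

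Stem cell surface markers fell as a list (adjusted p = 2.46e-05; adjusted p = 0.167 with an estimated correlation), with a median of −0.80 over 17 genes, or −0.95 relative to all probe sets. At unadjusted p, 9 were lower and 1 higher, and adjusted over the list alone the counts were also 9 and 1, against 0 over all probe sets. Besides Cd34, Adgrg1 and Kit, Itga2b, the integrin CD41, differed by −1.79 (SE 0.20) and Cd27, a TNF receptor family member, by −2.05 (SE 0.25). Jam3, a junctional adhesion molecule, had the opposite sign at 1.10 (SE 0.25). Erythroid markers, with a median of 1.51, and macrophage markers, with 1.17, rose on the same arrays, as they did beside every other list that fell.

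Other ETS factors fell as a list (adjusted p = 4.3e-08; adjusted p = 0.167 with an estimated correlation), with a median of −0.87 over 16 genes, or −1.02 relative to all probe sets. Adjusted over the list alone 8 were lower and 0 higher, and over all probe sets 0 passed. Fli1, a regulator of megakaryocyte and stem cell genes, read 10.50 ± 0.035 and 7.11 ± 0.79 (difference −3.40, SE 0.43). Elf1 differed by −2.64 (SE 0.31), Elf2 by −1.65 (SE 0.24), and Spi1, which encodes the myeloid and lymphoid factor PU.1, by −1.09 (SE 0.15). The median genomic span was 46.0 kb for this list, and the 25% of genes with the longest span had a lower median difference (0.078) than the 25% with the shortest (0.23).

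The study's own list fell (adjusted p = 1.1e-07; adjusted p = 0.167 with an estimated correlation), with a median of −0.91, or −1.05 relative to all probe sets, and all 10 measured genes below 0. Adjusted over the list alone 5 were lower, and over all probe sets 0 passed. The study picked these genes with these samples at hand, so the list is not independent evidence of its direction. Etv6, an ETS repressor needed by adult stem cells, read 10.25 ± 0.066 and 8.48 ± 0.053 (difference −1.77, SE 0.14, adjusted p = 0.173). Ep300, a histone acetyltransferase, differed by −2.08 (SE 0.52), the anti-apoptotic gene Bcl2 by −1.61 (SE 0.64) and its relative Bcl2l1 by −0.97 (SE 0.21). The DNA methyltransferase genes Dnmt3a, Dnmt3b and Dnmt1 differed by −1.50 (SE 0.39), −0.84 (SE 0.19) and −0.56 (SE 0.32). Zfx, a zinc finger factor of stem cell renewal, differed by −0.80 (SE 0.36), Mcl1 by −0.30 (SE 0.15) and Foxo3 by −0.21 (SE 0.21), with overlapping groups for Foxo3. Without deficient replicate 1 the Foxo3 log2 difference was −0.0029, the Dnmt1 log2 difference −0.17 and the Bcl2 log2 difference −0.98. With 1 array left out, Foxo3 ran from −0.41 to −0.0029, Dnmt1 from −0.95 to −0.17, Bcl2 from −2.24 to −0.98 and Zfx from −1.14 to −0.45. The values farthest from 0 for Foxo3, Dnmt1 and Bcl2, and −0.45 for Zfx, came without deficient replicate 2. Without control replicate 1 the Bcl2 log2 difference was −1.03 and the Zfx log2 difference −0.48, and without control replicate 2 Foxo3 stood at −0.14. The median genomic span was 75.5 kb for this list, in a table where the 25% of genes with the longest span had a lower median difference (0.078) than the 25% with the shortest (0.23).

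Megakaryocyte and platelet genes fell as a list (adjusted p = 1.19e-07; adjusted p = 0.167 with an estimated correlation), with a median of −0.71 over 14 genes, or −0.86 relative to all probe sets. At unadjusted p, 5 were lower and 0 higher, and adjusted over the list alone 3 were lower, against 0 over all probe sets. Pf4, a platelet chemokine, differed by −2.82 (SE 0.78), with 9.55 and 7.43 on the arrays labelled deficient, the tetraspanin gene Cd9 by −1.26 (SE 0.17), Nfe2, a platelet-forming transcription factor, by −1.005 (SE 0.24) and Vwf, von Willebrand factor, by −0.90 (SE 0.15). Itga2b and Vwf also belonged to the surface marker list.

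Chromatin regulators fell as a list (adjusted p = 4.14e-09; adjusted p = 0.167 with an estimated correlation), with a median of −0.70 over 40 genes, or −0.84 relative to all probe sets. At unadjusted p, 12 were lower and 2 higher, and adjusted over the list alone 2 were lower, against 0 over all probe sets. Dnmt1, Dnmt3a, Dnmt3b and Ep300 also belonged to the study's own list, so the 2 lists are not independent. Rnf2, a Polycomb ubiquitin ligase, differed by −1.58 (SE 0.20), the acetyltransferase genes Kat6b and Crebbp by −1.50 (SE 0.20) and −1.25 (SE 0.25), and Chd4, a nucleosome remodeller, by −0.70 (SE 0.15). Differences were lower for genes with a long genomic span than for short ones. The rank correlation of the difference with span was −0.22 across 19856 genes, and the 25% of genes with the longest span had a median of 0.078, against 0.23 for the 25% with the shortest. The median span was 54.0 kb for the chromatin list.

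DNA repair genes fell as a list (adjusted p = 0.000288; adjusted p = 0.175 with an estimated correlation), with a median of −0.25 over 38 genes, or −0.40 relative to all probe sets. At unadjusted p, 5 were lower and 1 higher, and adjusted over the list alone 0 passed. Atm, a DNA damage kinase, differed by −1.10 (SE 0.14), Lig3, a DNA ligase, by −0.83 (SE 0.15), Parp1 by −0.83 (SE 0.17) and Xrcc4, a factor of end joining, by −1.42 (SE 0.43). Without deficient replicate 1 the Xrcc4 log2 difference was −0.86, and the list median was much smaller in size, though still negative. The call ended without the dimmer 50% of probe sets (adjusted p = 0.107). Interferon-stimulated genes fell as a list (adjusted p = 1.89e-05; adjusted p = 0.167 with an estimated correlation), with a median of −0.31 over 30 genes, or −0.45 relative to all probe sets. At unadjusted p, 8 were lower and 0 higher, and adjusted over the list alone 0 passed. Irgm1, an immunity GTPase, differed by −1.61 (SE 0.28), Sp100 by −1.49 (SE 0.34), Oasl2 by −1.32 (SE 0.23) and Ddx58, the RNA sensor RIG-I, by −1.05 (SE 0.19). Both groups had received pIpC, itself an interferon inducer.

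G1 cyclins and CDKs fell as a list (adjusted p = 0.000907; adjusted p = 0.206 with an estimated correlation), with a median of −0.35 over 14 genes, or −0.49 relative to all probe sets. At unadjusted p, 5 were lower and 0 higher, and adjusted over the list alone 2 were lower. Ccnd2, cyclin D2, differed by −1.54 (SE 0.23), its partner kinase Cdk6 by −1.13 (SE 0.20), and the cell cycle inhibitors Rbl2 and Cdkn2d by −1.62 (SE 0.37) and −0.46 (SE 0.15). Quiescence and FOXO genes fell as a list (adjusted p = 0.00402; adjusted p = 0.233 with an estimated correlation), with a median of −0.25 over 17 genes, or −0.39 relative to all probe sets, and 4 lower and 0 higher at unadjusted p. Adjusted over the list alone 0 passed, and the call ended without the dimmer 50% of probe sets (adjusted p = 0.067). The list median was clearly smaller in size, though still negative, without deficient replicate 1. Sesn3, a sestrin, differed by −1.21 (SE 0.27), Ndn, necdin, by −0.99 (SE 0.31), Cat, catalase, by −0.58 (SE 0.15) and Tsc1, an mTORC1 inhibitor, by −0.47 (SE 0.14).

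Glycolysis genes fell as a list (adjusted p = 0.0152; adjusted p = 0.397 with an estimated correlation), with a median of −0.17 over 16 genes, or −0.31 relative to all probe sets. At unadjusted p, 2 were lower and 0 higher, and adjusted over the list alone 0 passed. Pkm, pyruvate kinase, differed by −0.81 (SE 0.16), Pfkp, a phosphofructokinase, by −0.75 (SE 0.15), Pdk1 by −0.65 (SE 0.25) and Slc2a1, a glucose transporter, by −0.37 (SE 0.15). Without control replicate 1 the Pdk1 log2 difference was −0.38. The call ended without control replicate 2 (adjusted p = 0.121), without deficient replicate 2 (0.0823), with cyclic loess (0.119), with a second quantile normalization (0.0579) and without the dimmer 50% of probe sets (0.218).

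Erythroid markers rose as a list (adjusted p = 7.61e-07; adjusted p = 0.167 with an estimated correlation), with a median of 1.51, or 1.37 relative to all probe sets, and all 12 measured genes above 0. Adjusted over the list alone 8 were higher and 0 lower, and over all probe sets 0 passed. Rhd, a blood group protein, read 7.64 ± 0.72 and 10.67 ± 0.0096 (difference 3.04, SE 0.39), and Ermap, another red cell surface protein, 7.49 ± 0.46 and 10.18 ± 0.17 (difference 2.69, SE 0.29). Trim10, an erythroid ubiquitin ligase, differed by 1.77 (SE 0.16), and Car1, carbonic anhydrase 1, by 1.26 (SE 0.15). The globin genes of the list had no single-gene probe set.

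Macrophage markers rose as a list (adjusted p = 1.89e-05; adjusted p = 0.319 with an estimated correlation), with a median of 1.17, or 1.03 relative to all probe sets, and all 15 measured genes above 0. Adjusted over the list alone 5 were higher, and over all probe sets 0 passed. Vcam1, an adhesion molecule of macrophages and stroma, read 6.66 ± 0.39 and 8.76 ± 0.40 (difference 2.10, SE 0.32). Cd5l, a macrophage scavenger protein, differed by 2.09 (SE 0.34), Mrc1, the mannose receptor, by 1.61 (SE 0.30) and Spic, a factor of red pulp macrophages, by 1.47 (SE 0.21). Stromal and endothelial markers rose as a list (adjusted p = 0.000791; adjusted p = 0.518 with an estimated correlation), with a median of 0.53 over 19 genes, or 0.39 relative to all probe sets. At unadjusted p, 10 were higher and 1 lower, and adjusted over the list alone 4 were higher and 1 lower. Besides Sparc and the shared Vcam1, Kdr, an endothelial VEGF receptor, differed by 0.82 (SE 0.16), and Tek, an angiopoietin receptor also found on stem cells, by −1.12 (SE 0.22).

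**Figure D2:**
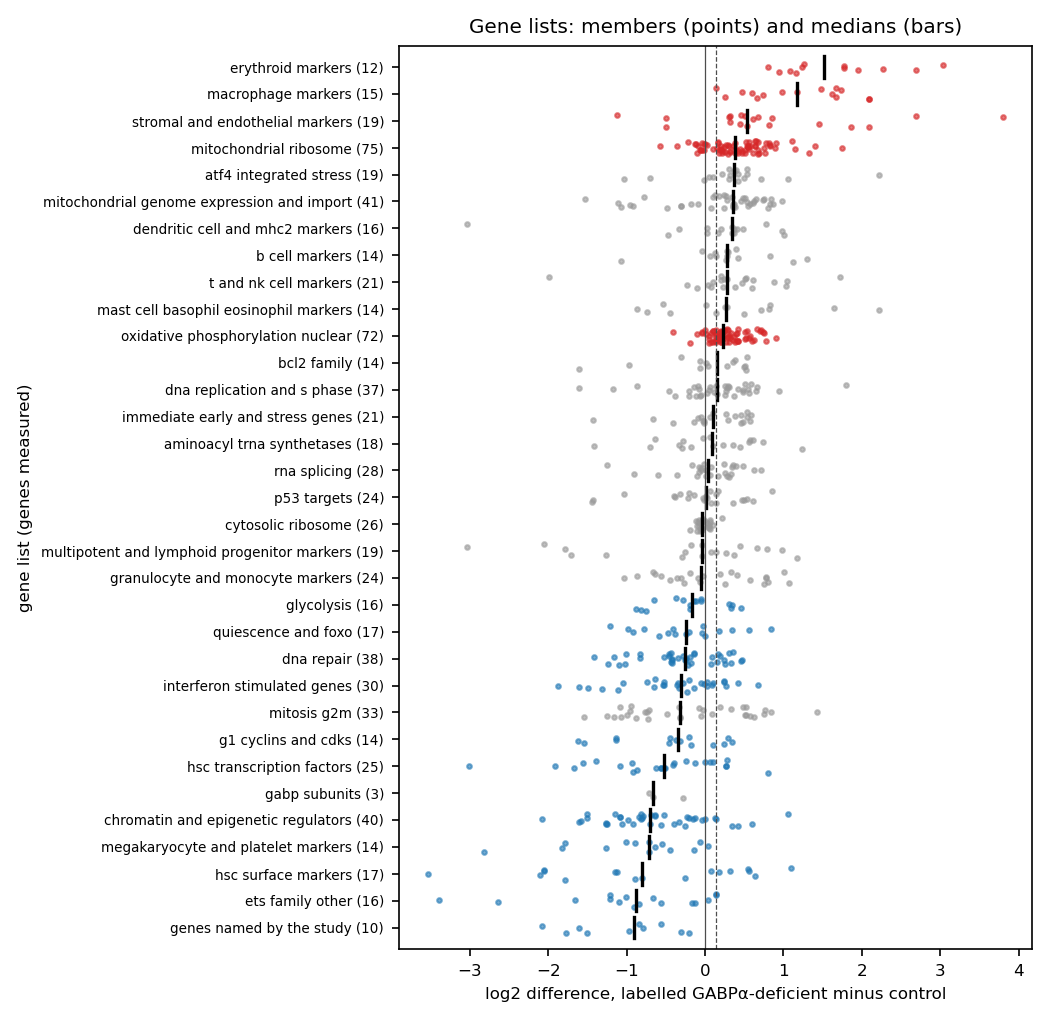
Log2 difference, arrays labelled GABPα-deficient minus control (horizontal axis), for the measured members of each of 33 gene lists (vertical axis), with points for genes, bars for medians and a dashed line at the median of all probe sets. Colour marks the 11 lists called lower and the 5 called higher with a preset correlation, from a median of −0.91 for the study's own list to 1.51 for erythroid markers.

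Mitochondrial ribosome genes rose as a list (adjusted p = 0.00101; adjusted p = 0.712 with an estimated correlation), with a median of 0.38 over 75 genes, or 0.24 relative to all probe sets. At unadjusted p, 15 were higher and 0 lower, and adjusted over the list alone 1 was higher. The median genomic span was 7.75 kb for this list, at the short end, where the median difference was higher (0.23) than at the long end (0.078). Erythroid markers (median 1.51) and macrophage markers (1.17) rose on the same arrays. Mrpl52 read 9.06 ± 0.12 and 10.80 ± 0.0071 (difference 1.74, SE 0.15), and Mrpl22, Mrpl35 and Mrpl14 differed by 1.15 (SE 0.23), 0.91 (SE 0.18) and 0.78 (SE 0.14). Nuclear-encoded oxidative phosphorylation genes, many of them with GABP binding sites in their promoters, rose as a list (adjusted p = 0.00753; adjusted p = 0.757 with an estimated correlation). Their median was 0.24 over 72 genes, or 0.091 relative to all probe sets, with 4 higher and 1 lower at unadjusted p and 0 adjusted over the list alone. Uqcr11 and Uqcrc1 of complex III differed by 0.70 (SE 0.17) and 0.75 (SE 0.22), Cox7a2 of complex IV by 0.54 (SE 0.15) and Atp5g1 of ATP synthase by 0.91 (SE 0.30). Without deficient replicate 1 neither list was called, with adjusted p = 0.621 for the mitochondrial ribosome and 0.737 for oxidative phosphorylation.

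Of the 17 lists that were not called, ATF4 targets had a median of 0.37 (camera adjusted p = 0.0701), with 1 lower and 4 higher at unadjusted p. The amino acid genes Asns and Slc7a5 were at 2.22 (SE 0.39) and 1.05 (SE 0.14), and Vldlr was at −1.04 (SE 0.31). That list passed in 8 alternatives, cyclic loess among them (adjusted p = 0.00511). Mitochondrial gene expression and import had a median of 0.35 (camera adjusted p = 0.223), with 1 lower and 6 higher at unadjusted p. The import receptor genes Tomm20 and Tomm70a went opposite ways, at 0.99 (SE 0.14) and −1.07 (SE 0.24). The list passed with cyclic loess (camera adjusted p = 0.00275), a second quantile normalization (0.0258) and without the dimmer 50% of probe sets (0.022). Mitosis genes had a median of −0.31 (adjusted p = 0.238), with 2 lower and 7 higher at unadjusted p, among them the centromere histone gene Cenpa at 1.42 (SE 0.27). Their median turned positive without deficient replicate 1. The direction of the list test turned upward with cyclic loess, fry, without the dimmer 50% of probe sets and without control replicate 1. DNA replication genes had a median of 0.15 (adjusted p = 0.935), with Ccne1, cyclin E1, at 1.80 (SE 0.33). Cytosolic ribosome genes had a median of −0.035 over 26 genes (adjusted p = 0.123), and they passed as lower with subtraction of column medians (adjusted p = 0.0116) and after span correction (adjusted p = 0.000126). The BCL2 family had a median of 0.16 (adjusted p = 1), with 1 lower and 3 higher at unadjusted p, among them the pro-apoptotic genes Bbc3 at 0.50 (SE 0.15) and Bcl2l11 at 0.52 (SE 0.16).

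Medians of the p53 targets, splicing genes, tRNA synthetases and immediate early genes were 0.019, 0.039, 0.084 and 0.10, with adjusted p of 0.227, 0.735, 0.755 and 0.935. Multipotent and lymphoid progenitor markers had a median of −0.038 (adjusted p = 0.142), with Il12a at −1.78 (SE 0.40). Granulocyte and monocyte markers had a median of −0.046 (adjusted p = 0.31), with Csf3r, the G-CSF receptor, at −1.04 (SE 0.22) and Cd14 at 0.78 (SE 0.19). B cell markers had a median of 0.29 (adjusted p = 0.185), and T and NK cell markers 0.28 (adjusted p = 0.0919; 0.0349 without the dimmest 25% of probe sets), with Gzmb, granzyme B, at 1.73 (SE 0.20). Dendritic cell markers had a median of 0.35 (adjusted p = 0.418), and mast cell, basophil and eosinophil markers 0.27 (adjusted p = 1). Camera's direction was downward while the median was above 0 for p53 targets, splicing genes and mast cell, basophil and eosinophil markers. For granulocyte and monocyte markers it was downward while the mean was 0.059.

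Leaving out 1 array also changed some of these calls. Without deficient replicate 1, T and NK cell markers and B cell markers passed as higher, and granulocyte and monocyte markers as lower. Without deficient replicate 2, ATF4 targets and mitochondrial gene expression and import passed as higher, and multipotent and lymphoid progenitor markers as lower. Without control replicate 1, mitochondrial gene expression and import and T and NK cell markers passed as higher. Without control replicate 2, ATF4 targets passed as higher and mitosis genes as lower.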

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

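The span correction was chosen after the results were seen, and the other alternatives were planned. Under every normalization, filter, weighting and left-out array tried, 0 probe sets passed an adjusted p under 0.05 in limma, with lowest adjusted p from 0.109 to 0.522, and 0 passed at 0.1. With an unadjusted p and a fold of at least 1.5, 1707 were lower and 1281 higher. The number higher at an unadjusted p, 2360, became 1191 with cyclic loess, 1537 with column medians subtracted, 964 without the dimmer 50% of probe sets, where fewer were tested, 715 after span correction, and 714 to 2198 with 1 array left out. Fewer were also tested after span correction, since only probe sets with 1 gene symbol and a known span entered it. Probe sets with 1 gene symbol had 1688 higher without that correction, so the fall from 2360 to 715 is partly the smaller set. The number lower stayed between 1348 and 2349. Except for the smaller number tested, the cause was not tested.

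With an estimated correlation 0 lists were lower and 0 higher, and fry called 5 lower and 1 higher, in place of 11 and 5. The 6 lists called by fry were other ETS factors, the study's own list, interferon-stimulated genes, stem cell surface markers, stem cell transcription factors and erythroid markers. Under cyclic loess and a second quantile normalization 15 of the 16 calls were kept, without the dimmer 50% of probe sets 13, and 14 to 16 with 1 array left out. The 16 calls were all kept with column medians subtracted, array weights, a trend and robust settings and span correction, which also called ATF4 targets (adjusted p = 0.0384) and, as lower, cytosolic ribosome genes (0.000126). The Gabpa difference ran from −1.42 to 0.0021 with 1 array left out, where deficient replicate 1 decided its sign, and Gabpb2 from −0.65 to 0.098. After span correction the Rplp1 log2 difference was −0.010 in place of 0.21. The cause was not tested.

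The replicate numbers pair nothing that the labels state, and arrays with the same number did not deviate together (correlation across probe sets −0.088). With a replicate block 1341 probe sets were higher and 1666 lower at an unadjusted p, the lowest adjusted p was 0.522, and no other call changed, the 16 lists included. The arrays carry no detection calls used here, so levels of dim probe sets, such as Sfrp4 at 4.92 on the control arrays, were not set against a background.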

Other observations

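The tests on erythroid cells, on a lower share of the main cell type and on amplification were chosen after the result was seen, as was the span correction. For the span trend as a whole cause, exchanged labels and Gabpa after span correction, the patterns had been seen, but the bounds were written before each test was run. The marker lists in the next paragraph were also written after the data had been seen. A first form of the erythroid comparison, on erythroid genes picked from these values, was dropped because the picking fixed its outcome.

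Lists of further cell types gave untested medians. Late neutrophil genes had a median log2 difference of 0.77, with 11 of 12 above 0, and plasma cell genes 0.93, with 11 of 12 above 0. The late neutrophil median was clearly smaller, though still positive, without control replicate 2. Mast cell and basophil genes had a median of 0.60 (9 of 10 above 0), adipocyte genes 0.64 (7 of 7) and pre-B cell genes 0.28 (8 of 10). The pre-B cell median rested on deficient replicate 2, and deficient replicate 1 taken alone showed no such shift of the median. Of these genes, 6 late neutrophil, 2 plasma cell, 9 mast cell and basophil, 1 adipocyte and 10 pre-B cell genes also belonged to a list fixed earlier. The broader fixed lists were not called: granulocyte and monocyte markers had a median of −0.046 (13 of 24 below 0, camera adjusted p = 0.31), and mast cell, basophil and eosinophil markers 0.27 (adjusted p = 1). Among mast cell genes the larger differences rested mainly on deficient replicate 1, where Mcpt4 read 10.16 and Tpsb2 9.68, against 6.75 and 6.71 on deficient replicate 2 (both genes chosen after their values were seen). The median of all probe sets was 0.15. Among variable segments of the immunoglobulin kappa chain, probe set 10545180 read 4.10 and 5.04 on the control arrays and 8.13 and 8.53 on those labelled deficient. Probe set 10538882 read 6.09 and 4.01 on the control arrays, 4.51 on deficient replicate 1 and 10.67 on deficient replicate 2.

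Erythroid, macrophage and stromal markers were higher on the arrays labelled deficient. A lower share of the main cell type, which would raise the markers of all other types alike, may account for part of this and stays open. The same lower share would also lower genes of the main cell type. It may thus account for part of the falls in the stem cell lists, which was not tested. Erythroid list genes above the table's median level (10 genes, mean 1.80, SD 0.71) exceeded late neutrophil genes (9 genes, mean 0.60, SD 1.00) by a log2 of 1.198 (two-sided permutation test over genes, p = 0.00215; genes are not independent replicates). This decides nothing, since 5 of the 9 neutrophil genes had a high level on the control arrays, above the table's upper quartile, which would hide a small share, and 1 gene took their mean from 0.91 to 0.60. Erythroid cells in the sorted fraction, which a lineage gate would remove, are a candidate explanation: the probe sets shared by the adult α-globin genes, among the most abundant red cell transcripts, were higher by a mean log2 of 3.905, at 12.00 or 11.95 and above on the arrays labelled deficient. A change of erythroid genes within stem and progenitor cells, which also express Gata1 and Car1, through the genotype named in the design, stays open and untested.

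Genes with a long genomic span had lower differences (median 0.078 for the longest 25%) than those with a short one (0.23 for the shortest 25%), with a rank correlation of −0.22 across genes. RNA integrity or amplification that differed between samples may have contributed: replicates differed along span too, at 0.147 between the controls and −0.106 between those labelled deficient, and the smaller was 0.483 of the size between groups. It cannot be told apart from genotype here, because that ratio fell between the bounds set for either answer and no RNA quality measure was used here. The trend as the whole cause of the list calls was argued against, since all 16 called lists kept direction and call after span correction.

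The Gabpa probe set did not separate the groups. A swap of control replicate 2 with deficient replicate 2 stays open. The labels as given had 4225 probe sets at an unadjusted p under 0.05 and the exchanged labels 972. The ratio of 4.347 was past the bound written against a swap. It shows only that arrays sharing a label resembled each other, which any other difference between the groups, such as a different mix of cells, would also give. A span trend that hides a difference was argued against, since after span correction Gabpa differed by −0.8115 (SE 0.671) and 1 array labelled deficient still lay above a control. Probes outside the deleted exons, cells that escaped deletion and a small change stay open, none of them tested.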
